A study of Mus musculus with 8 samples.

How the data were processed

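The expression table deposited by the authors listed 23346 mouse genes with 6 values per gene, 1 for each library. The values were size-factor-normalized counts: gene read counts that the authors had divided by 1 factor per library. The unit was treated as a normalized signal. Every value was a whole multiple of its library's smallest step, to within 0.001 of a whole number, so the whole reads were recovered for 100.0% of values. The deposited table also held the mean signal of each group, a log2 fold change of control over knockout, a p-value and an adjusted p-value from the authors. Their log2 fold change was positive where the control mean was higher in 99.68% of genes. The authors' adjusted p-value was 1 in 6791 genes, and 1 p-value was missing. DESeq2 run here on the recovered reads gave an adjusted p to 16555 of 23346 genes, so these values may stand for missing ones. The authors' fold changes and p-values served only as a comparison.

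The deposited peak lists held 1 line per peak. Per the column order of the deposited format, each peak had a score equal to 10 times the −log10 q, a ratio giving the fold enrichment at the summit over the caller's background, a −log10 p and a −log10 q. Peak positions were read as deposited on the mouse build mm10. Gene positions came from the deposited expression table. On build GRCm38, the same assembly, 19387 of these genes could be compared with a RefSeq annotation. Of these, 99.95% lay on the same chromosome, with a median difference of 13 bp between starts. A name table held 99.91% of the gene identifiers, with the same symbol in 99.25%. In that deposited file 25 symbols had been stored as dates, and all 25 were restored from the gene identifier.

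Per the submitters' processing notes, the RNA libraries went through HISAT2 2.1.0, Bowtie2 2.2.3 and HTSeq 0.6.0. The same notes name BWA, SAMtools, MACS2, deepTools and DESeq2 for the ChIP libraries, without versions. The role and order of these tools are not stated. DESeq2 run here on the recovered RNA reads gave 4174 genes with an adjusted p under 0.05, 2127 higher and 2047 lower in knockouts. The authors' RNA table has the same counts, so DESeq2 may be the tool behind its p-values. The gene annotation release, the tool behind the size factors, the input control, the handling of duplicate reads and the peak threshold are not given in the sources used here.

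The comparison of knockout with control used limma with a trend on log2(value + 1). Genes with a mean of at least 1 in either group were kept, and the Benjamini-Hochberg method gave adjusted p-values with a threshold of 0.05. All fold changes are knockout over control. The plan had assumed a table of raw counts, and its stated fallback for normalized values became the test used here. Tests for counts (edgeR, DESeq2 and limma voom) were run on the recovered reads as alternatives. The tests, gene lists, alternatives and rule for naming genes were fixed before the data were examined, apart from those named as added later.

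Each value is given as mean ± SD of the 3 libraries in a group, and SE is the standard error of a log2 fold change from limma. Fold changes in words are ratios of the mean normalized counts, so they can differ slightly from the fitted log2 values. A fold against a group with 0 reads was computed against a floor of 3 reads over the group and is a lower bound. For genes with 1 to 3 reads in a group, the ratio of control to knockout is given with a 95% counting interval. Intervals and floors cover counting error only. The labels do not say whether replicates came from separate animals or separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

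The 30 gene lists covered macrophage programs, other processes and cell type markers. The macrophage programs were classical activation (M1), alternative activation (M2), interferon response, NF-kB feedback and targets, MHC class II presentation, chemokines and their receptors, macrophage identity, lipid handling and ETS family members. The processes were cell cycle, cholesterol synthesis, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, immediate early genes, lysosome, the unfolded protein and amino acid stress response, extracellular matrix, and genes of mitochondrial DNA. Marker lists covered neutrophils, T and NK cells, B cells, dendritic cells, mast cells and basophils, erythroid cells, megakaryocytes and platelets, stromal cells and fibroblasts, endothelium, adipocytes and osteoclasts. The last list held Y-linked genes and Xist. Of 490 symbols in the lists, 454 were tested, and 1 symbol had more than 1 gene identifier. Lists were compared with all other genes by camera from limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 29 lists. An estimated correlation and fry were alternatives. A range beside an adjusted p covers that list's alternatives, left-out libraries included.

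Genes were named by rule. Ets1 came first. Then came the 10 higher and 10 lower called genes with the largest log2 fold change, a mean of at least 5 in the higher group and no overlap between groups. From each list, up to 4 measured members with the smallest p followed. Peaks were named by fold enrichment and by position at these genes. Lyz1, Lyz2 beside it, Ltf, Csf3r, Ighm, Cd79b, Mki67, Tagln, Ngp, S100a8, Neat1, Malat1 and the members that complete a count of 5 or fewer were named outside the rule, after their values were seen.

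A peak was shared if it overlapped a peak of the other list by at least 1 bp. A peak was at a gene's start site if its summit lay within 1 kb of it, with 1 start site per gene. Alternatives for the windows were 3, 10 and 50 kb. Shares of single peak lists have Wilson 95% intervals. Peaks at changed genes were tested with Fisher's exact test, two-sided, over 20553 genes. They were also compared with 10000 random gene sets matched on mean expression in 20 bins. As a background for position, peaks were moved by 50 kb.

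On simulated data with 50 changed genes per fold, limma recovered 31 genes at 1.5-fold, 43 at 2-fold, 50 at 4-fold and 50 at 8-fold. It made 10 false calls among 18918 genes. The changed genes all had a mean of at least 20 normalized counts, and as many rose as fell. Recovery at lower counts, or with mostly losses, was not simulated. Camera called 0 of 20 unchanged lists and 2 of 2 changed lists. The simulated genes were independent of each other, so this does not cover lists of correlated genes, such as the stromal markers (estimated correlation 0.523). Alternatives chosen after seeing the data were edgeR with TMM, edgeR with the replicate block, a filter at a mean of 5, both total scalings, the removal of a gene length trend, the list test after total scaling and the peak limit at a −log10 q of 20. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.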

Results

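RNA was sequenced from bone marrow-derived macrophages, which are macrophages grown from mouse bone marrow in medium with M-CSF. The 3 control libraries came from mice with floxed Ets1 alleles. The 3 knockout libraries came from mice that also carried Lyz2-cre, which removes the floxed segment in myeloid cells. Ets1 is a transcription factor of the ETS family, known from lymphocytes. All mice were males aged 8 weeks, and cells were cultured for 7 days with 10 ng/ml M-CSF and 10% serum. Ets1 ChIP-seq, which maps where the protein lies on DNA, covered wild-type macrophages after M1 or M2 polarization, with 1 library per state. Those cells were fixed in 1% formaldehyde for 10 min, and the libraries took 15 PCR cycles and 150 bp reads. The agents used for polarization are not named in the labels.

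The control libraries held 20259175, 17706149 and 17868912 recovered reads on genes, and the knockout libraries held 17570356, 19591768 and 16897873. Between 18980 and 20217 genes were detected per library. The control libraries had 20217, 19773 and 19843 detected genes, and the knockout libraries had 18980, 19176 and 18992. The 50 most abundant genes took between 17.7% and 18.0% of reads in every library. Spread between libraries went beyond counting noise in both groups. Chi-square per degree of freedom between pairs of libraries was 12.9, 37.5 and 11.6 in controls and 4.38, 5.41 and 3.10 in knockouts. The first principal component held 42.1% of the variance. All controls lay between −69.3 and −45.0 on it, and all knockouts between 53.2 and 57.4.

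The first comparison asked what loss of Ets1 changed in macrophages for which the labels name no polarization. Ets1 itself (ENSMUSG00000032035, chromosome 9, 32636221 to 32757820 on mm10, plus strand) fell 4.43-fold. Its normalized count was 3282 ± 389 (SD, n = 3) in controls and 742 ± 90.6 in knockouts. The 3 controls lay at 3641, 3337 and 2869, and the 3 knockouts at 825, 755 and 645. The log2 fold change from limma was −2.15 (SE 0.11, adjusted p = 3.93e-07). A total of 2111 reads remained in the knockout libraries, against 10582 in controls. The table counts reads per gene, so reads from the floxed segment cannot be separated from the rest of the gene.

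In all, 4298 of 20595 tested genes passed the test, 2142 higher and 2156 lower in knockouts. Large changes were mostly losses: 216 genes rose and 1106 fell by an absolute log2 fold change of at least 1. Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688), an adhesion molecule that binds leukocytes, fell 14.2-fold from 986 ± 104 to 69.4 ± 2.21 (n = 3 per group). Its log2 fold change was −3.80 (SE 0.12, adjusted p from limma 2.79e-09). Marco (ENSMUSG00000026390), a scavenger receptor, rose 3.21-fold from 10632 ± 552 to 34113 ± 683, with a log2 fold change of 1.68 (SE 0.08). Igf2bp3, an RNA-binding protein, rose 6.37-fold from 39.7 ± 6.94 to 253 ± 31.9.

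Igf2bp3 was among the 10 genes with the largest rises. Of the others, Arfgef3 rose 7.89-fold and Avil, which codes for the actin-binding protein advillin, rose 7.23-fold. Eef1a2, a translation elongation factor, was at 0 reads in controls and rose at least 8.97-fold. The long RNA 2410003L11Rik rose at least 7.14-fold and the small nuclear RNA Gm25605 at least 5.97-fold, both from 0 reads. Calb2, which codes for calretinin, had 1 read in controls and 42 in knockouts, a ratio of control to knockout of 0.000520 to 0.124. The processed pseudogene H2afy3 had 3 and 35 reads, a ratio of 0.0149 to 0.240. Stfa1, of a multigene family, had 1 and 23 reads (0.000932 to 0.237). Fgf22, a growth factor, had 3 and 30 reads (0.0173 to 0.284), and its adjusted p of 0.0120 became 0.0645 without control replicate 2 and 0.0734 without knockout replicate 1.

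The 10 largest falls included B cell and immunoglobulin genes. Igha, an immunoglobulin heavy chain gene, had 362 reads in controls and 0 in knockouts, at least 108-fold lower. Ighg2c had 215 reads and 1 read, a control to knockout ratio of 33.7 to 7536. Immunoglobulin genes share sequence, so single members are uncertain. Ms4a1, which codes for CD20, fell 28.5-fold. Tnfrsf13c, the receptor for BAFF, fell 20.1-fold. Rasgrp3 had 171 and 2 reads (ratio 20.6 to 629), and Gimap3 had 100 reads and 1 read (ratio 15.5 to 3524). Also among them were Prss34, a mast cell and basophil protease that fell 50-fold, Wisp2, a secreted protein that fell 30.6-fold, and the neutrophil chemokine Cxcl5, with 144 and 2 reads (ratio 17.3 to 530).

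**Figure D1:**
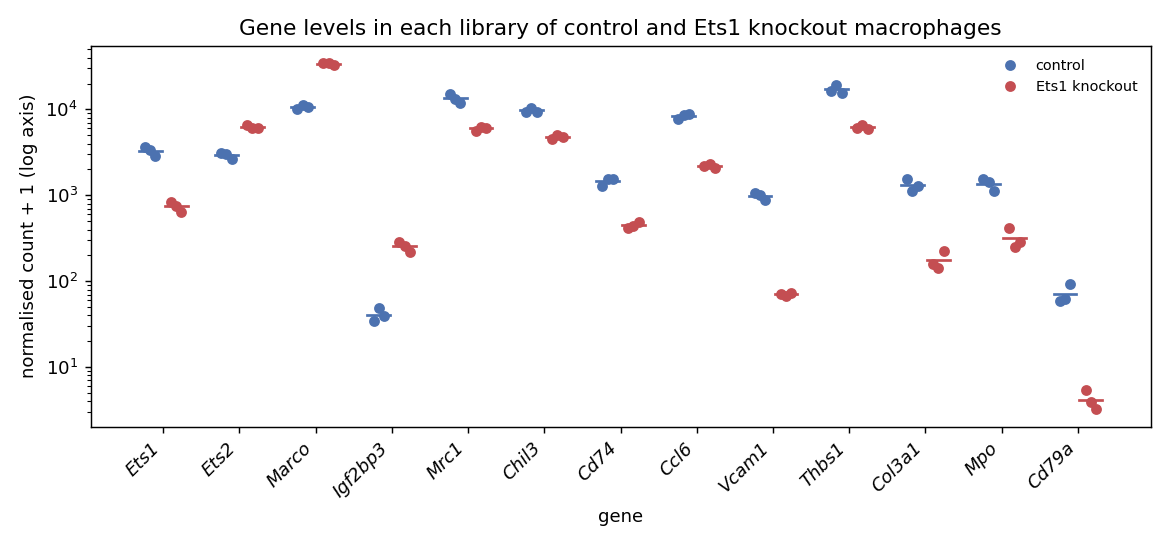
Normalized read count plus 1 of 13 genes on a log axis, each point a library and each line the mean of a group of 3. In Ets1 the controls lie between 2869 and 3641 and the knockouts between 645 and 825; Marco and Ets2 are higher in all 3 knockouts.

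A total of 7574 tested genes (36.8%) had no overlap between the groups' libraries, against 10% by chance. Among the called genes this was 4237 (98.6%). The number of called genes fell to 2029 without control replicate 2, 2221 without knockout replicate 1, 2054 without knockout replicate 2 and 2490 without knockout replicate 3. Genes called higher numbered 959, 930, 873 and 1136 in these fits, and genes called lower 1070, 1291, 1181 and 1354. The split between directions rests on the scaling. Scaling to total reads shifted the median log2 fold change of all genes by −0.132 and gave 1187 higher and 3255 lower genes, so that 26.7% of calls were higher instead of 49.8%. With upper-quartile scaling in edgeR it was 36.3%. The authors' deposited table has 4174 genes with an adjusted p under 0.05, of which 3999 were also called here, all in the same direction.

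Genes of classical (M1) activation moved in both directions. Of 27 tested members, 5 rose, 6 fell and 16 did not pass. The 5 that rose were Marco, Tnf, Tlr2, Gpr18 and Acod1, which codes for the enzyme that makes itaconate and went from 1514 to 2446. Ccl5, a chemokine for T cells and monocytes, fell 6.67-fold from 168 ± 40.5 to 25.2 ± 1.90. Ccl2, which draws monocytes, fell 2.13-fold from 741 to 348. Adjusted over the list alone, 5 rose and 8 fell. Camera did not call the list (adjusted p = 0.430). Scaled to total reads, 2 rose and 9 fell.

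Genes of alternative (M2) activation fell more often than they rose. Of 23 members 1 rose (Tgfb1), 10 fell and 12 did not pass; adjusted over the list alone, 3 rose and 11 fell. The mannose receptor gene Mrc1 fell 2.23-fold from 13443 ± 1616 to 6019 ± 306, with a log2 fold change of −1.15 (SE 0.09). Chil3, a chitinase-like protein, fell 2.03-fold from 9727 ± 590 to 4791 ± 263. Clec10a, a lectin, fell 3.55-fold from 703 ± 168 to 198 ± 20.2. Cd163, the scavenger receptor for haemoglobin with haptoglobin, went from 595 to 317. Camera placed the list lower than other genes (adjusted p = 0.000239). That became adjusted p = 0.139 with an estimated correlation (range 0.000105 to 0.139 over its alternatives). With scaling to total reads, 0 rose and 11 fell. In the same libraries dendritic cell markers had a median log2 fold change of −0.51, endothelial markers of −1.31 and stromal markers of −1.72, and Clec10a and Flt1, a list member, are also known from dendritic and endothelial cells.

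Of 12 MHC class II genes, which present antigen to T cells, 8 fell, 4 did not pass and 0 rose; adjusted over the list alone, 10 fell. Cd74, the invariant chain, fell 3.26-fold from 1461 ± 168 to 448 ± 39.6. H2-Aa fell 4.93-fold from 264 to 53.5. H2-Eb1 and H2-Ab1 had log2 fold changes of −1.91 and −1.64, with some uncertainty because H2 genes share sequence. The list's median log2 fold change was −1.58 and its camera adjusted p 2.16e-06. It had adjusted p = 0.139 with an estimated correlation (range 5.01e-07 to 0.139). In the same libraries, B cell markers had a median log2 fold change of −3.57 and dendritic cell markers of −0.51, and both cell types are known to carry MHC class II.

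Chemokines and their receptors fell in 15 of 27 cases, 12 did not pass and 0 rose; adjusted over the list alone, 17 fell. Ccl6 fell 3.85-fold from 8410 ± 625 to 2183 ± 110, with a log2 fold change of −1.94 and an adjusted p of 4.92e-08. Ccl7, a monocyte chemokine, went from 634 to 236. The camera adjusted p was 1.56e-08. The list had adjusted p = 0.194 with an estimated correlation (range 1.37e-09 to 0.194). Ccl5 is also among the T and NK cell markers, which had a median log2 fold change of −0.99, or −0.40 with genes at 0 reads placed at their bound. Medians were −0.81 for neutrophil, −1.72 for stromal and −2.08 for megakaryocyte and platelet markers, but 0.01 for osteoclast markers.

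Extracellular matrix and remodelling genes, Vcam1 among them, had 22 members, of which 2 rose (Icam1 and Itga5), 10 fell and 10 did not pass; adjusted over the list alone, 4 rose and 10 fell. Thbs1, a matrix protein that acts on TGF-beta, went from 17121 ± 2086 to 6191 ± 364, a log2 fold change of −1.46. The basement membrane collagen Col4a2 went from 275 to 75.2. Camera gave the list an adjusted p of 2.27e-05, against adjusted p = 0.241 with an estimated correlation (range 1.60e-07 to 0.241). After total-read scaling, 0 rose and 14 fell. Stromal and fibroblast markers, whose source cells make matrix, had a median log2 fold change of −1.72 in the same libraries.

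NF-kB feedback genes rose more often than they fell. Of 19 members 9 rose, 3 fell and 7 did not pass, and adjusted over the list alone the counts were again 9 and 3. Nfkbiz, a nuclear IkB protein, went from 8882 to 14049, and Tnip1, a partner of the deubiquitinase A20, from 3454 to 5062. The inhibitor gene Nfkbie, with a log2 fold change of −0.90, the adaptor Traf1 (−1.18) and Ier3 fell. By camera the list's adjusted p was 0.00732, against adjusted p = 0.466 with an estimated correlation (range 0.00147 to 0.466). Scaled to total reads, 5 rose and 3 fell. In the unfolded protein and amino acid stress response 7 of 16 members rose, 1 fell (Ddit4) and 8 did not pass, against 11 and 2 adjusted over the list alone. Herpud1, of the degradation machinery of the endoplasmic reticulum, went from 2894 to 4337, and asparagine synthetase (Asns) from 410 to 727. This list had a camera adjusted p of 0.00116 and adjusted p = 0.139 with an estimated correlation (range 0.000259 to 0.139). Under total-read scaling 5 rose and 2 fell.

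The ETS family, to which Ets1 belongs, had 7 of 19 members higher, 3 lower and 9 not past the test, with the same 7 and 3 counts adjusted over the list alone. Ets2, the closest relative of Ets1 (ENSMUSG00000022895, chromosome 16, 95702075 to 95721051), rose 2.13-fold from 2930 ± 270 to 6235 ± 281, a log2 fold change of 1.09 (SE 0.08). Etv5 went from 1011 to 1519. Besides Ets1, the repressor Etv3, with a log2 fold change of −0.38, and Etv4 fell. Camera did not call the list (adjusted p = 0.250, direction up), with a median of 0.04 and a mean of −0.01. These values include Ets1 itself, the targeted gene, and the list was not tested without it. With scaling to total reads, 5 members rose and 4 fell. Immediate early genes had 15 members: the Krueppel-like factors Klf6 and Klf2 rose, Ier2 and Fos fell, and 11 did not pass. Adjusted over the list alone, 2 rose and 3 fell, and camera gave an adjusted p of 0.765. After total-read scaling, 2 of them rose and 5 fell.

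Interferon response genes moved apart. Of 30 members 4 rose (Ddx58, Oas3, Stat2 and Ifih1), 6 fell and 20 did not pass, the same 4 and 6 adjusted over the list alone. Ddx58, the RNA sensor RIG-I, had a log2 fold change of 0.38. Oasl1 went from 618 to 319 and Ifi44 from 782 to 379. Irf7, a main interferon regulator, fell by a log2 of 0.61, with an adjusted p of 0.00601 that became 0.0606 without control replicate 2. Camera did not call the list (adjusted p = 0.593). Without control replicate 1 it was called, with an adjusted p of 0.00189, and without control replicate 3 its direction was up, with an adjusted p of 0.388. Under total-read scaling 1 rose and 6 fell.

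Macrophage identity genes split as well. Of 20 members 3 rose (Adgre1, Maf and Lyz2), 7 fell and 10 did not pass; adjusted over the list alone, 3 rose and 8 fell. Adgre1, which codes for F4/80, went from 68331 to 101870. The complement gene C1qa went from 16158 to 9014, the monocyte gene Ly6c2 from 654 to 245, and Folr2, a folate receptor of resident macrophages, had a log2 fold change of −1.14. The list's camera adjusted p was 0.0231, and 0.0527 without knockout replicate 3. It had adjusted p = 0.217 with an estimated correlation (range 0.00374 to 0.217). Scaled to total reads, 3 rose and 13 fell. In the same libraries neutrophil and precursor markers had a median log2 fold change of −0.81 and dendritic cell markers of −0.51, but osteoclast markers of 0.01.

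Lipid handling genes moved in both directions. Of 18 members 3 rose (Lpl, Abcg1 and Nr1h3), 6 fell and 9 did not pass; adjusted over the list alone, 4 rose and 7 fell. Lipoprotein lipase (Lpl) went from 21873 to 41685, a rise of 1.91-fold. Spp1, which codes for osteopontin, went from 33573 to 16321, and the lipid receptor Trem2 from 3747 to 1773. The fatty acid carrier Fabp5 had a log2 fold change of −0.84. Camera did not call the list (adjusted p = 0.475). With scaling to total reads, 2 rose and 8 fell.

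Glycolysis and hypoxia genes had 22 members, of which 1 rose (Hk2), 7 fell and 14 did not pass; adjusted over the list alone, 2 rose and 9 fell. Vegfa, the vascular growth factor, went from 2583 to 1188, and the glycolytic enzyme Tpi1 had a log2 fold change of −0.38. The call of Hk2 was lost without each of control replicate 2 (adjusted p = 0.0915) and knockout replicates 1 (0.0986), 2 (0.0824) and 3 (0.0616). The camera adjusted p was 0.0172, and 0.0544 without knockout replicate 3. It had adjusted p = 0.5 with an estimated correlation (range 0.000218 to 0.5). After total-read scaling, 1 rose and 14 fell.

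Cell cycle genes had 28 members, of which 5 fell (Birc5, Rrm2, Cdc20, Plk1 and Tyms), 0 rose and 23 did not pass, with 5 lower adjusted over the list alone. Birc5, which codes for survivin, had a log2 fold change of −0.68, and Cdc20, an activator of the anaphase-promoting complex, of −0.69. The call of Plk1 was lost without control replicate 2 (adjusted p = 0.0721) and without knockout replicate 2 (0.0786). Mki67, a proliferation marker, was at 3252 and 3897 (adjusted p from limma 0.235). Camera did not call the list (adjusted p = 0.250), but did without knockout replicate 1 (0.0465). Under total-read scaling 9 members fell and the list was called (0.0491).

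In the cholesterol synthesis list 1 of 20 members rose (Lss), 3 fell (Cyp51, Sc5d and Fdps) and 16 did not pass, also when adjusted over the list alone. The lanosterol demethylase Cyp51 had a log2 fold change of −0.41, with an adjusted p of 0.00927 that became 0.0694 without control replicate 2, 0.0533 without knockout replicate 2 and 0.0587 without knockout replicate 3. The calls of Lss (adjusted p-values of 0.0571 to 0.144) and Sc5d (0.0579 to 0.146) were lost when any library except control replicate 1 was left out, and that of Fdps (0.0680 to 0.169) when any except control replicate 3 was. Scaled to total reads, 0 rose and 6 fell. The list's median was 0.03 and its mean −0.09, and camera gave the direction down with an adjusted p of 0.924. Without control replicate 1, control replicate 2 or knockout replicate 3 the direction was up, with adjusted p-values of 0.901, 0.843 and 0.836. Of 20 lysosome genes 3 rose, among them Laptm5, 7 fell and 10 did not pass, against 5 and 8 adjusted over the list alone. The protease gene Ctsl had a log2 fold change of −0.55. The lysosome median was 0.03 and the mean −0.02, and camera gave the direction down with an adjusted p of 0.924. With scaling to total reads, 2 rose and 8 fell. The direction of the list was up without control replicate 2 (0.897) and without knockout replicate 3 (0.961).

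Of 22 nuclear genes of oxidative phosphorylation 2 rose (Atp5a1 and Sdha), 3 fell (Ndufa4, Ndufb5 and Uqcrq) and 17 did not pass; adjusted over the list alone, 3 rose and 3 fell. The calls of the falls were lost when any library except control replicate 1 was left out, with adjusted p-values of 0.0665 to 0.177. The rise of Atp5a1 was lost without control replicate 2 and without each knockout replicate (0.0628 to 0.0815). The median was 0.04 and the mean −0.05, and camera gave the direction up with an adjusted p of 0.774, but down without control replicate 1 (0.488) and after scaling to total reads (0.459), where 0 rose and 3 fell. Genes of mitochondrial DNA rose in 3 of 13 cases (mt-Nd1, mt-Nd5 and mt-Nd6, subunits of complex I), while 10 did not pass and 0 fell; adjusted over the list alone, 5 rose. Of these, mt-Nd1 went from 21003 to 33661, and its adjusted p of 0.00442 became 0.0552 without control replicate 2 and 0.0556 without knockout replicate 2. The call of mt-Nd6 was lost without control replicate 2 (0.0889) and knockout replicates 2 (0.0870) and 3 (0.0741), and that of mt-Nd5 without control replicate 2 and each knockout replicate (0.0837 to 0.121). For the mitochondrial list camera gave an adjusted p of 0.00990, and 0.0638 without control replicate 3 and 0.287 by fry. It had adjusted p = 0.5 with an estimated correlation (range 0.000114 to 0.5). The share of reads from mitochondrial genes was 1.57%, 1.28% and 1.10% in controls and 1.57%, 1.72% and 1.74% in knockouts.

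**Figure D2:**
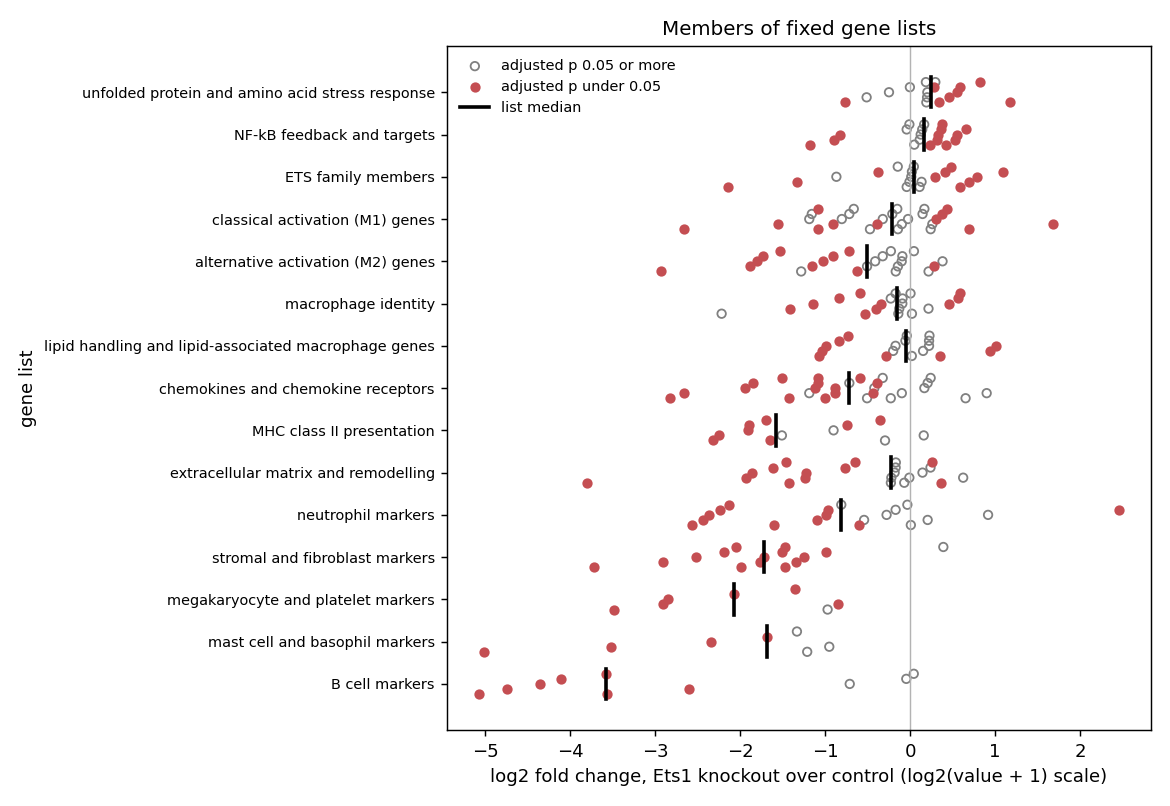
Log2 fold change (knockout over control) of the tested members of 15 gene lists, each point a gene, red where the adjusted p is under 0.05, with a bar at the list's median. Medians lie at −1.58 for MHC class II and 0.24 for the unfolded protein and amino acid stress response.

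Several lists of markers of other cell types were lower in the knockout libraries. Stromal and fibroblast markers fell in 14 of 15 cases, also when adjusted over the list alone, and Tagln did not pass. Cxcl12, a chemokine of marrow stroma, fell 13.9-fold from 254 ± 26.4 to 18.3 ± 0.351. Col3a1, a fibrillar collagen, fell 7.45-fold from 1306 ± 211 to 175 ± 42.7. Pdgfra, a receptor of mesenchymal cells, went from 588 to 102, and all 15 markers stayed at a mean of at least 5 in knockouts. By camera the stromal list had an adjusted p of 2.36e-16, against adjusted p = 0.193 with an estimated correlation (range 5.62e-21 to 0.193).

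B cell markers fell in 7 of 10 cases, also when adjusted over the list alone, and 3 did not pass. Cd79a, part of the B cell receptor, went from 70.7 to 3.17, while Cd79b (573 and 589, adjusted p from limma 0.775) and Ighm (2819 and 2726, adjusted p 0.731) did not pass. For the B cell list camera gave an adjusted p of 9.85e-06, against adjusted p = 0.201 with an estimated correlation (range 7.40e-07 to 0.201). Of 12 T and NK cell markers 4 fell (Ccl5, Gzmb, Lck and Nkg7) and 8 did not pass, against 5 lower adjusted over the list alone. The kinase gene Lck had a log2 fold change of −2.77, and its call was lost without control replicate 3 (adjusted p = 0.0569) and knockout replicate 1 (0.0512). The call of Gzmb was lost without control replicate 2 (0.0603), and that of Nkg7 when any library except knockout replicate 1 was left out (0.0618 to 0.114). The camera adjusted p was 0.0379, and 0.124 without control replicate 1 and 0.154 after scaling to total reads. The list had adjusted p = 0.201 with an estimated correlation (range 0.00201 to 0.201).

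Neutrophil and precursor markers fell in 10 of 19 cases, 1 rose (Stfa2) and 8 did not pass; adjusted over the list alone, 11 fell and 1 rose. Neutrophil elastase (Elane) went from 710 to 138, proteinase 3 (Prtn3) from 494 to 91.4 and myeloperoxidase (Mpo) from 1363 ± 213 to 315 ± 84.8, all proteins of primary granules. Other members of the list, named after their values were seen, did not move alike. Ngp fell from 7005 to 3586 and the calprotectin gene S100a8 from 3657 to 1683. Lactoferrin (Ltf) was at 3381 and 3383 (adjusted p from limma 0.960) and the G-CSF receptor gene Csf3r at 4326 and 4238 (0.810), and neither passed. A difference between stages was not tested. By camera the neutrophil list had an adjusted p of 3.43e-07, against adjusted p = 0.194 with an estimated correlation (range 4.13e-09 to 0.194).

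Mast cell and basophil markers fell in 4 of 7 cases (Prss34, Kit, Cpa3 and Ms4a2) and 3 did not pass, against 6 lower adjusted over the list alone. Kit, the receptor for stem cell factor, had a log2 fold change of −1.69. The call of Ms4a2 was lost without control replicates 2 (adjusted p = 0.0768) and 3 (0.0746) and knockout replicates 2 (0.0877) and 3 (0.0784). For these markers camera gave an adjusted p of 0.000239, against adjusted p = 0.139 with an estimated correlation (range 0.000117 to 0.139). Megakaryocyte and platelet markers fell in 6 of 7 cases, with Gp9 not past the test, and in 7 adjusted over the list alone. Itga2b, an integrin of platelets, went from 187 to 25.1, and the platelet chemokine gene Ppbp from 268 to 61.3. Their camera adjusted p was 9.85e-06, against adjusted p = 0.194 with an estimated correlation (range 1.50e-06 to 0.194). Dendritic cell markers fell in 3 of 11 cases (Ccr7, Dpp4 and Bst2), also when adjusted over the list alone, and 8 did not pass. Ccr7, a homing receptor, went from 90.9 to 30.9. The call of Dpp4 was lost without control replicate 2 (0.0582), and that of Bst2 without control replicate 2 and each knockout replicate (0.0852 to 0.115). Their camera adjusted p was 0.0401, with 0.107 after scaling to total reads, 0.0776 without control replicate 3 and 0.0544 without knockout replicate 3. They had adjusted p = 0.201 with an estimated correlation (range 0.0150 to 0.201).

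Endothelial markers fell in 3 of 7 cases (Tek, Cdh5 and Kdr) and in 6 adjusted over the list alone. The adhesion gene Cdh5 had a log2 fold change of −1.51, and its call was lost without any of control replicates 1 (adjusted p = 0.0558), 2 (0.162) and 3 (0.0524) and knockout replicates 1 (0.0784) and 3 (0.107). The call of Tek was lost without control replicates 1 (0.0937) and 2 (0.0774) and knockout replicates 2 (0.104) and 3 (0.0939), and that of Kdr when any library except knockout replicate 1 was left out (0.0723 to 0.158). The endothelial list's camera adjusted p was 0.0117, against adjusted p = 0.279 with an estimated correlation (range 0.00400 to 0.279). Of 4 erythroid markers only Hba-a1 passed, also when adjusted over the list alone. It was at 0 reads in knockouts and at least 4.10-fold lower, with an adjusted p of 0.0504 without control replicate 3. Camera gave the erythroid list an adjusted p of 0.309. The only adipocyte marker tested, Plin4, was at 3.32 and 4.90 and did not pass. Of 10 osteoclast markers the transcription factor gene Nfatc1 rose, Itgb3 and Mmp9 fell and 7 did not pass, with 2 higher and 2 lower adjusted over the list alone. The call of Mmp9 was lost without control replicate 2 (0.0603) and knockout replicate 2 (0.0515). Camera gave the osteoclast list the direction up with an adjusted p of 0.924, while fry gave the direction down (0.736), as did the fits without control replicate 3 (0.768) and knockout replicate 1 (0.947). Of 4 Y-linked genes Kdm5d passed, also when adjusted over the list alone, with a log2 fold change of 0.29, but not after scaling to total reads (0.16, adjusted p = 0.213) and not when any library except control replicate 1 was left out (0.0953 to 0.169). The Y-linked list had a camera adjusted p of 0.376.

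Camera called 17 of 29 tested lists, 14 lower and 3 higher. With an estimated correlation it called 0, with adjusted p-values of 0.139 to 0.5 for those 17 lists, while fry called 18. Fry asks whether the members of a list move in 1 direction on balance and does not compare them with other genes.

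The ChIP-seq lists addressed where Ets1 lies in M1 and M2 macrophages. The M1 list held 23089 peaks with a median fold enrichment of 5.68 and a median width of 323 bp, and the M2 list 22640 peaks with a median of 5.90 and 425 bp. With 1 library per state and no read counts per peak, M1 and M2 were not tested against each other. Of the M1 peaks 14737, or 63.8% (Wilson 95% interval 63.2 to 64.4), overlapped an M2 peak. Of the M2 peaks 14377, or 63.5% (62.9 to 64.1), overlapped an M1 peak. Overlap followed peak strength. Among the weakest peaks, below the first quartile of fold enrichment, it was 29.4% in M1 and 30.1% in M2, and among the strongest, above the last quartile, 96.5% and 96.4%. Peaks with an overlap had a median fold enrichment of 6.89 in M1 and 7.15 in M2, against 4.57 and 4.71 for peaks of a single list. Of peaks with a −log10 q of at least 20 in 1 list, a limit added after the data were seen, 99.3% of M1 and 99.4% of M2 peaks overlapped any peak of the other list. With both lists limited to their top 5000 peaks the overlap was 77.1% and 76.6%.

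The highest shared peak of the M1 list lay on chromosome 12 at 120028661 to 120028966, outside RefSeq genes, with a fold enrichment of 44.8 in M1 and 36.7 in M2. A shared peak on chromosome 16 at 98107503 to 98107675 had 44.6 in M1 and 37.3 in M2. The highest peak of the M1 list alone lay on chromosome 4 at 153153037 to 153153214 (fold 34.1). Another M1 peak without an overlap lay within Flt1, a VEGF receptor gene, on chromosome 5 at 147611435 to 147611620 (fold 21.8). The highest peak of the M2 list alone lay on chromosome Y at 90767778 to 90768000 (fold 19.7). No regions prone to false signal were removed here, and the sequence at summits was not checked. These peaks, and the overlap of the strongest peaks, therefore need not reflect Ets1 binding. A total of 35.7% of M1 and 36.8% of M2 summits lay within 1 kb of a start site, against 3.98% to 4.25% of peaks moved by 50 kb. In gene bodies lay 40.3% and 39.9%, against 60.8% to 61.9% of moved peaks, and between genes 24.0% and 23.3%, against 33.9% to 35.1%. Shared peaks lay at start sites in 49.7% of cases in both lists, and peaks of a single list in 11% (M1) and 14.5% (M2).

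**Figure D3:**
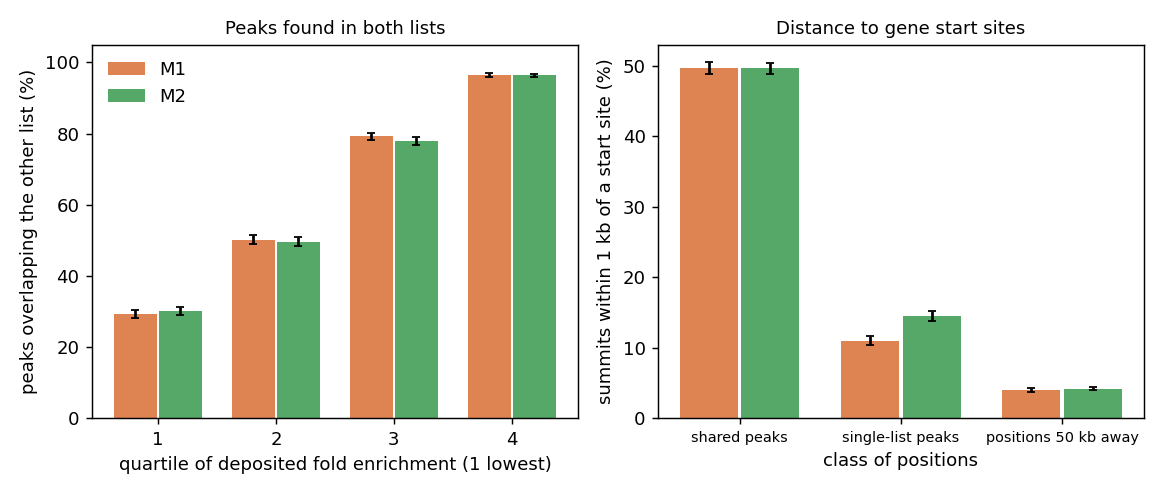
Percent of Ets1 peaks that overlap a peak of the other list, by quartile of fold enrichment, for M1 and M2. Beside it is the percent of summits within 1 kb of a start site, for shared peaks, single-list peaks and positions 50 kb to the left. Overlap goes from 29.4% to 96.5% in M1 and from 30.1% to 96.4% in M2.

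Ets1 had no peak within 1 kb of the 1 start site used for it, at 32636221, but peaks lay in its body. Whether these peaks lie at other start sites of Ets1 was not checked. On chromosome 9, M1 and M2 peaks overlapped near 32652312 to 32652522 (fold 4.26 and 5.91), near 32695832 to 32696140 (fold 7.45 and 7.43) and near 32709822 to 32710026 (fold 10.5 and 8.85). A peak at 32685765 to 32686070 was in the M1 list alone (fold 5.57). The promoter of Ets2, which rose in the knockout, had a peak in both lists at 95701900 to 95702915 (fold 10.7 in M1 and 11.1 in M2). So did Etv5 (13.8 and 11.9), Klf6 (14.4 and 10.0), Herpud1 (9.57 and 9.15), Ccl2 (7.57 and 9.37) and Thbs1 (7.00 and 7.79). Cd74 (4.08), H2-Ab1 (4.40), Adgre1 (5.16) and Tnip1 (3.69) had a start-site peak in the M1 list alone, and Trem2 (3.72), Ccl7 (3.70) and Asns (4.13) in the M2 list alone. These single-list peaks were weak. Their −log10 q was 2.26 to 4.80 in M1 and 2.07 to 2.99 in M2, against list medians of 5.87 and 7.28. Marco, Mrc1, Chil3, Clec10a, Vcam1, Ccl6 and Spp1 had none within 1 kb. Of 132 named genes 40 had a start-site peak in both lists, 8 in M1 alone, 7 in M2 alone and 77 in neither. Such peaks were common: 43.2% of genes not called in the knockout comparison had one in M1 and 44.4% in M2. Of 19 ETS family members 13 had one in M1 and 13 in M2. Random lists matched on expression had medians of 14 and 14 (percentiles 40.1 and 32.0).

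Of 27 M1 activation genes 14 had a start-site peak in the M1 list and 13 in the M2 list, 11 of them in both. Random lists matched on expression had medians of 15 and 16. Within 10 kb the counts were 22 and 25, against 19 and 20. Cd86, a co-stimulatory ligand (fold 7.54), and the chemokine gene Cxcl1 (3.71) had it in M1 alone, and Ccl4 (5.31) and Gpr18 (5.02) in M2 alone. The M1 peak at Tnf (4.39) overlapped an M2 peak whose summit lay farther away. Of 23 M2 activation genes 7 had a start-site peak in M1 and 8 in M2, 5 in both, against matched medians of 12 and 12. The IL-4 receptor gene Il4ra (5.30) had it in M1 alone, and Ccl24 (5.98), Socs2 (5.12) and Flt1 (5.12) in M2 alone. The M1 peak at Egr2 (5.50) overlapped an M2 peak.

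Among other lists, NF-kB genes had start-site peaks in 16 (M1) and 15 (M2) of 19 cases, against matched medians of 15 and 15 (percentiles 77.2 and 53.2), and the stress response in 14 and 14 of 16, against 11 and 12 (94.8 and 93.1). Cell cycle genes had them in 23 and 26 of 28 cases, against 20 and 20 (90.2 and 99.5). Among lists that camera placed lower, though not with an estimated correlation (adjusted p-values of 0.194, 0.241 and 0.139), chemokines and receptors had 6 and 9 of 27, against matched medians of 15 in both, extracellular matrix 6 and 7 of 22 (16 and 17), and MHC class II genes 6 and 3 of 12, against 6 and 6 (percentiles 50.4 and 2.21). Within 10 kb MHC class II genes had 9 and 10, against 8 and 8. Stromal, B cell and megakaryocyte markers had 0 in both lists, against 9 and 9, 4 and 4, and 2 and 3.

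The last comparison asked whether genes that changed without Ets1 had Ets1 peaks at their start sites. Genes that rose had them more often than genes that were not called: 1482 of 2135 (69.4%) had an M1 peak, against 43.2% of 16263. The odds ratio was 2.99 (2.71 to 3.29; Fisher's exact test, adjusted p = 7.76e-117), and for M2 peaks the share was 71.0% against 44.4% (odds ratio 3.06, adjusted p = 2.48e-119). Genes that fell had them less often: 38.3% had an M1 peak (odds ratio 0.819, Fisher's exact test, adjusted p = 2.64e-05) and 41.0% an M2 peak (0.868, adjusted p = 0.00231). Expression level changes the first result. Against random genes of equal expression, a median of 1536 genes with an M1 peak stood against the 1482 found, at percentile 0.07, and for M2 a median of 1570 against 1515, at percentile 0.02. The genes that fell lay at percentile 0 in both lists. The comparison was not repeated with genes called under another scaling. Scaling to total reads called 1187 genes higher instead of 2142.

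By size of change, peaks were fewest at strongly changed genes. Of 214 genes that rose by a log2 of at least 1, 23.8% had an M1 peak, against 41.6% of matched genes, and of 1105 genes that fell as much 17.3%, against 35.0%. For the 1921 genes that rose less the share was 74.5%, against 75.3% (percentile 15.7), and for the 1050 that fell less 60.5%, against 68.4%. Of the 10 genes with the largest rises Igf2bp3 and Fgf22 had an M1 peak, and of the 10 with the largest falls Prss34 did, while 0 in either set had an M2 peak. Genes are not independent replicates, and RNA came from macrophages for which no polarization is named, while ChIP came from polarized ones. The genes that fell include markers of other cell types, among them 14 of 15 stromal markers, and stromal, B cell and megakaryocyte markers had 0 start-site peaks. Matching on expression does not separate genes by cell of origin. Whether such genes account for the low shares was not tested.

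**Figure D4:**
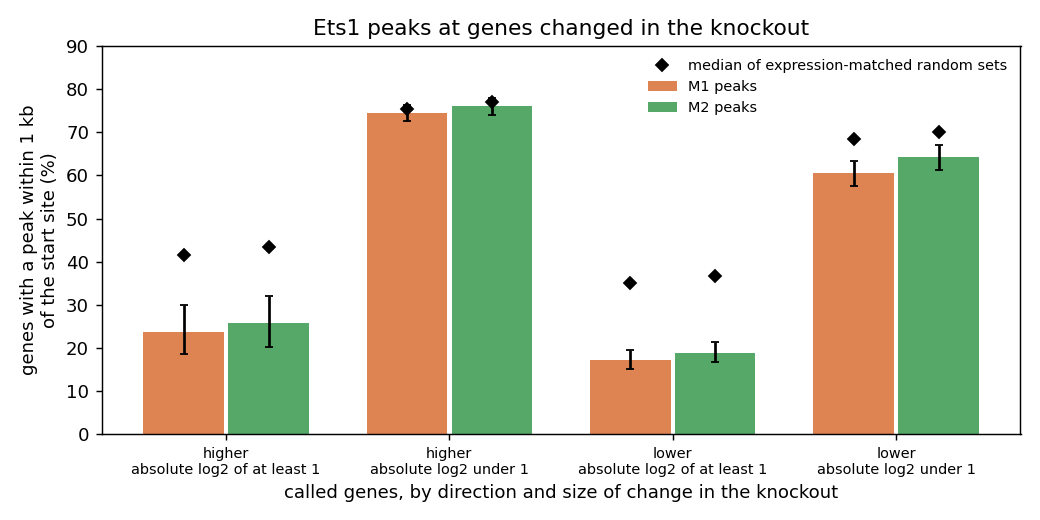
Percent of genes with an Ets1 summit within 1 kb of the start site, by direction and size of change in the knockout, for M1 and M2 peaks, beside random genes matched on expression. Genes with a log2 change of at least 1 lie below their matched genes, at 23.8% against 41.6% for rises and 17.3% against 35.0% for falls in M1.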

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

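Ets1 kept its direction and its call under every setting run, with log2 fold changes of −2.24 to −2.05 when each library was left out. Besides the fit reported, 22 settings were run, 6 of which left out a library. Of 2745 values for 131 named genes, 2519 kept direction and side of the threshold, 183 kept the direction but no longer passed, 19 newly passed and 24 reversed. The losses include those under the limit of an absolute log2 fold change of at least 1, where genes with smaller changes fail by construction. Over the 6 left-out libraries alone, 676 of 786 kept both, 103 no longer passed and 5 reversed. Called genes kept the same sign wherever another setting also called them. Genes removed by a filter, or without an adjusted p in DESeq2, gave no value. The word counts at summits were not run, since no genome sequence was used here, and keeping only assembled chromosomes changed nothing. On simulated data 31 of 50 genes changed 1.5-fold were recovered.

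An absolute log2 fold change of at least 1 gave 1322 called genes, 216 higher and 1106 lower, since that setting keeps a subset. Scaling to total reads gave 1187 higher and 3255 lower genes, and scaling without the 50 most abundant genes gave 1213 higher genes. Both shift fold changes in 1 direction by construction, and that direction comes from the libraries. Normalized totals were 16790343 to 17844885 in controls and 18887618 to 19116732 in knockouts. Leaving out each library gave 2029 to 5716 called genes, 873 to 2976 higher and 1070 to 2740 lower. The lowest count was without control replicate 2 and the highest without control replicate 1. Without knockout replicate 1 it was 2221, without knockout replicate 2 it was 2054 and without knockout replicate 3 it was 2490. A group of fewer libraries is part of that setting, and why control replicate 1 raised the count when left out was not tested.

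Log2 fold changes of Y-linked genes near 0 changed sign. Scaled to total reads they were −0.032 (Uty), −0.117 (Ddx3y) and −0.129 (Eif2s3y), and without the 50 most abundant genes −0.027, −0.112 and −0.125. For Ddx3y they were −0.022 with edgeR TMM, −0.067 with upper quartile, −0.021 without a filter, −0.050 with the stricter filter and −0.021 with voom. For Eif2s3y they were −0.038 with TMM, −0.006 with RLE, −0.084 with upper quartile, −0.038 without a filter, −0.066 with the stricter filter and −0.034 with voom. With each library left out Ddx3y ranged from −0.002 to 0.042 and Eif2s3y from −0.049 to 0.082. None of these values passed the test. Both total scalings lowered fold changes, with median shifts of −0.132 and −0.127, which gives the sign changes under them. The cause of the other sign changes was not tested.

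The replicate block treated libraries of equal number as 1 block. It gave 5374 called genes with limma, 2652 higher and 2722 lower, and 4993 with edgeR, a setting added after the data were seen. Libraries of equal number had correlations of 0.210, 0.084 and 0.129 across 11550 genes after removal of group means, and 5 of 6 libraries correlated best with the library of their own number. With the replicate block in edgeR, Ddx3y was at −0.022 and Eif2s3y at −0.035. In the list tests with the replicate block, T and NK cell markers no longer passed (adjusted p = 0.0734). Osteoclast markers (0.948) and nuclear oxidative phosphorylation (0.948) changed direction, and the cause was not tested.

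With an estimated correlation camera called 0 lists. The adjusted p-values were 0.201 for B cell markers, 0.139 for MHC class II, 0.466 for NF-kB, 0.201 for T and NK cells, 0.139 for M2 activation, 0.194 for chemokines, 0.201 for dendritic cells, 0.279 for endothelium, 0.241 for extracellular matrix, 0.5 for mitochondrial DNA and 0.5 for glycolysis. They were 0.217 for macrophage identity, 0.139 for mast cells, 0.194 for megakaryocytes, 0.194 for neutrophils, 0.193 for stromal cells and 0.139 for the unfolded protein response. The estimated correlation was below the preset 0.01 for some of these lists, among them MHC class II (−0.0102), mast cells (−0.101) and T and NK cells (−0.0328). A larger correlation is not the reason there. That setting also takes its degrees of freedom from the 6 libraries, where the preset takes them from the number of genes. This raises p-values at any correlation, and its share in each change was not tested. Scaled to total reads, T and NK cells (0.154) and dendritic cells (0.107) no longer passed, cell cycle (0.0491) passed and oxidative phosphorylation (0.459) changed direction. With fry, Y-linked genes (0.00653) and erythroid markers (0.0101) passed, mitochondrial DNA did not (0.287) and osteoclast markers changed direction (0.736). The cause was not tested.

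With each library left out, list adjusted p-values ranged as follows. T and NK cells had 0.0231 to 0.124 (highest without control replicate 1), cell cycle 0.0465 to 0.723 (lowest without knockout replicate 1) and dendritic cells 0.0259 to 0.0776 (highest without control replicate 3). Mitochondrial DNA had 0.000114 to 0.0638 (highest without control replicate 3), glycolysis 0.000449 to 0.0544 and macrophage identity 0.0102 to 0.0527 (both highest without knockout replicate 3). Interferon genes had 0.00189 to 0.897 and passed without control replicate 1. Cholesterol synthesis had 0.411 to 0.901, lysosome 0.633 to 0.961, osteoclast markers 0.768 to 0.947 and oxidative phosphorylation 0.155 to 0.866. Directions changed for cholesterol synthesis without control replicates 1 and 2 and knockout replicate 3, and for interferon without control replicate 3. They also changed for lysosome without control replicate 2 and knockout replicate 3, for osteoclast markers without control replicate 3 and knockout replicate 1, and for oxidative phosphorylation without control replicate 1. The cause was not tested.

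Overlap of M1 peaks with M2 peaks, and of M2 with M1, was 49.6% and 50.6% when 50% of both peaks had to be shared, and 54.5% and 55.6% with summits within 200 bp. It was 79.3% and 69.1% at a −log10 q of at least 5 and 77.1% and 76.6% for the top 5000 peaks. Of peaks with a −log10 q of at least 20 in 1 list, 99.3% of M1 and 99.4% of M2 peaks overlapped any peak of the other list, and with equal numbers of peaks in both lists it was 64.9% of M1 peaks. Stricter rules for overlap lower it by construction. Within 3 kb of a start site lay 41.9% of M1 peaks (56.0% of shared, 17.1% of single-list peaks) and 43.1% of M2 peaks (55.7% and 21.2%), as a wider window must give. At a −log10 q of at least 5 it was 49.3% of M1 peaks (54.5% and 15.0%) and 46.9% of M2 peaks (53.3% and 18.2%). Against genes of equal expression, genes higher in the knockout had fewer start-site peaks instead of more, at percentiles 0.07 (M1) and 0.02 (M2), so the excess in Fisher's exact test goes with expression level. Within 10 kb, 81.5% of M1 activation genes (22 of 27) had an M1 peak and 92.6% (25) an M2 peak, against matched medians of 19 and 20, at percentiles 90.4 and 99.8. In that window MHC class II genes had 9 and 10 of 12, against matched medians of 8 and 8 (percentiles 75.4 and 89.2).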

Other observations

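The tests of B cell, stromal, T and NK and mast cell presence, of an even loss of other cells' RNA, of library size, of reads shared between Lyz1 and Lyz2 and of the share of the most abundant genes were chosen after the results were seen, as was the removal of a gene length trend.

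The lysozyme genes moved apart. Lyz1 on chromosome 10 (117287797 to 117292868) fell from 1523 to 66.3 normalized counts, with a log2 fold change of −4.50 and an adjusted p from limma of 1.89e-10. Its neighbour Lyz2, the main macrophage lysozyme and the site of the Cre insertion, rose from 138290 to 203340, with a log2 fold change of 0.56. The long nuclear RNA Neat1, a scaffold of paraspeckles, fell from 15568 to 6452, while Malat1 was at 7343 and 10244 and did not pass (adjusted p from limma 0.158).

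Start-site peaks were fewer than in matched random lists at some further lists and not at others. Of 30 interferon response genes 17 had an M1 peak and 14 an M2 peak at the start site, against a median of 23 for both, at percentiles 1.20 and 0.01. Of 18 lipid handling genes 8 had an M1 peak and 10 an M2 peak, against 14 and 14 (percentiles 0.25 and 2.41). Of 20 macrophage identity genes 12 had an M1 peak, against a median of 14 (percentile 12.1), and 8 an M2 peak, against 15 (percentile 0.08). Cholesterol synthesis genes had 16 and 17 against 14 and 14, lysosome genes 16 and 17 against 15 and 15, nuclear oxidative phosphorylation genes 18 and 18 against 17 and 17, and immediate early genes 12 and 11 against 10 and 10.

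Camera placed markers of stromal cells, B cells, T and NK cells (4 of 12 fell) and mast cells lower in the knockout libraries, but with an estimated correlation it called none of these lists (adjusted p-values of 0.139 to 0.201), and the groups' read totals had a ratio of 0.968, which argues against library size. Of markers with a mean over both groups of at least 5, 86.7% of 15 stromal, 75% of 4 T and NK, 100% of 5 mast cell and 77.8% of 9 B cell markers lay below a log2 fold change of −1. These shares restate the fall and were looked at after it was seen, so other cells in the control cultures and an effect of Ets1 loss on these genes within macrophages cannot be told apart. Of 71 markers of 8 lists 67.6% lay more than 2 SE from their common log2 fold change of −1.07. This spread cannot decide on an even loss of RNA from all other cells through a higher share of macrophages. It assumes that macrophages supply none of the markers, while some, such as Cd79b and Csf3r, hardly moved. An even loss and losses that differ by cell type could both account for the fall and stay open. An effect of Ets1 loss on the growth of other marrow cells also stays open and was not tested.

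For the lysozyme genes, reads shared between the paralogs may be considered. Lyz2 gained 65050 normalized counts while Lyz1 lost 1457, a ratio of 44.6, which argues against moved reads as the source of the Lyz2 gain. The ratio cannot decide on the fall of Lyz1, since its whole loss is small beside that gain. A block of strain variants around the Cre insertion could also alter Lyz1. Within 5 Mb of Lyz2 12 of 70 tested genes were called (17.1%), against a median of 21% in 20536 such windows, at percentile 21.1. That explanation and an effect of Ets1 loss cannot be told apart, since a variant of Lyz1 alone needs no other changed neighbour. The insertion itself goes with the knockout group in every library.

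The number of called genes was 4298 for the real groups and at most 0 for the other splits, and 1 of the 10 splits of the 6 libraries gave as many, but splits of 6 libraries are too few for a share under 0.05. The mean share of reads in the 50 most abundant genes differed between the groups by 0.071 percentage points, below the SD of 0.155 between libraries, which argues against a few abundant genes; scaling to total reads kept 77.8% of the calls with these genes and 78.4% without them. After removal of a gene length trend 81.1% of the calls remained. A length trend could therefore account for some calls, and which of the lost calls it accounts for cannot be told apart, since a call lost after a correction does not show that the trend was technical. An effect of Ets1 loss on the remaining genes stays open, as do differences between animals or cultures that go with the groups.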
